A study of Mus musculus with 8 samples.

How the data were processed

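RNA was sequenced from liver macrophages of C57BL/6 mice kept on a normal diet (ND, 4 libraries) or a western diet (WD, 4 libraries). C57BL/6 is a common inbred mouse strain. Western diet is the labels' own term, and its composition and duration are not given in the sources used here. Per the labels' protocols, cells were lysed in Trizol, polyadenylated RNA was enriched with oligo(dT) beads and fragmented, and cDNA was made with random hexamer primers before adaptor ligation, size selection and PCR. The series design gives 4 mice per diet, which equals the number of libraries per group. How macrophages were isolated and whether the libraries kept strand information are not given in the sources used here. Each library was placed in its group by its diet label. The library labels are numbers (31, 33, 34 and 35 for ND, and 21, 24, 25 and 29 for WD), so any order of collection or preparation that these numbers follow would coincide with diet.

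The data used here are 1 table made by the authors, with no value for any single library. Per the file headers it lists genes regulated in a group written WDV, and the name under which the table was deposited sets this group against one written NDV. The V is not explained in the sources used here. The groups were taken to be the WD and ND libraries, an assumption behind every value below. The authors' columns carry, per the file headers, the names that DESeq2, a count model for sequencing data, gives its results. The submitters' processing notes name HISAT2, STAR, featureCounts, StringTie, edgeR, DESeq and STAR-Fusion and the build mm10, without roles, order or versions. For each gene the deposited signal is a mean normalized read count, which in such a table is averaged over the libraries after division by size factors. The deposited log2 fold change is WD over ND, with its standard error (SE) on the same log2 scale. The deposited test score is the fold change divided by its SE, and the largest departure from that ratio was 7.1e-08. The deposited p-value and its Benjamini-Hochberg adjusted p-value complete each row. The same file holds the authors' enrichment of Gene Ontology (GO) and KEGG terms among listed genes with a positive fold change, whatever their adjusted p, with a Benjamini p-value per term. For GO terms the deposited fold enrichment ratio was also used, and it could be recomputed from the gene numbers deposited beside it. The fold enrichments of KEGG terms were not used here.

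The table was checked for what it had been filtered on. Every listed gene had a p-value below 0.05 (largest, 0.04995) and an absolute log2 fold change above 1 (smallest, 1.00011). A gene outside the table may have missed either limit or may not have been measured, and no statement is made on which. The adjusted p was empty for 77 genes. Their mean counts were at most 2.02, and every gene with an adjusted p had a mean count of at least 2.03. These 77 genes were not counted as passing. Because library totals and counts per library are not in the table, depth per library is unknown. No SD, replicate range, left-out library, other normalization, count model or permutation of libraries could be computed here. Precision is therefore given by the authors' SE. The median SE of log2 fold change was 0.88 in the 25% of listed genes with the lowest mean counts and 0.21 in the 25% with the highest.

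An adjusted p-value equals the p-value times the number of tested genes divided by the gene's rank, unless a later gene sets it. The number of tested genes was therefore sought as the whole number that makes most ranks whole within 0.02. It was 17531, which gave whole ranks for 91.0% of listed genes with an adjusted p. On 1 simulated table of 15000 genes the same step returned 15000, and 99.9% of its whole ranks were the true ones.

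A gene was called higher or lower in WD at an adjusted p below 0.05, as fixed before the data were examined for a table already filtered on p. All calls thus use the authors' adjusted p-values, with a limit set here, and carry a log2 fold change above 1 in size. The authors' own list, at an unadjusted p below 0.05, holds 706 higher and 1680 lower genes. Before the data were examined, 33 gene lists were also fixed, 9 of them markers of other cell types that a liver macrophage preparation could hold. For lists with at least 5 members in the table, higher against lower was compared with all other listed genes by a two-sided Fisher's exact test, adjusted by Benjamini-Hochberg over the 10 lists tested. After the data were seen, a one-sided hypergeometric test was added. It asked whether more members had been called than expected among the 17531 tested genes, adjusted over 66 tests (33 lists in both directions). It takes every list member as tested, which can only understate an enrichment. Both tests treat genes as independent, which co-regulated genes are not, and a correlation between genes could not be estimated without values per library. Counts "adjusted over the list alone" take members outside the table as having a p-value of 1. On simulated lists of 20 genes drawn from the 2386 genes of the table, the direction test called 3.5% of lists with no preference and 100.0% of lists that were 90% higher. Most lists tested had fewer listed members than that, and lists of mostly lower genes were not simulated. The 100.0% therefore does not carry over to them.

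Genes were named by a rule fixed in advance. It took the 10 largest rises and 10 largest falls among called genes with a mean count at or above the table's median of 37.5, leaving out predicted and pseudogene symbols, and up to 4 called members of each list with the smallest p. It also took Adgre1, Clec4f, Timd4 and Alb where listed. The planned condition that groups must not overlap needs values per library and was not applied. A gene that the rule picked is not reported here. Genes outside this rule were chosen after their values were seen. In the main account these are Igfbp4, Smchd1, Fn1, Hp, Ptprb, Stab2, Kdr, Dnase1l3, Clec4g, Mx2, Cyp4a14, Steap4 and Pkhd1. All 2386 gene IDs matched GENCODE M21, the GRCm38 annotation that corresponds to mm10, and 2376 had the same symbol there. Coordinates are 1-based from that annotation. Where genes have near-identical copies (the Ly6, Oas, Ifi200, Cyp4a and immunoglobulin families), reads could be split between copies and single values are uncertain. Calculations used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.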

Results

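Gene expression was compared between liver macrophages of mice fed a western diet (WD, 4 libraries) and of mice fed a normal diet (ND, 4 libraries). The question was which genes differ with diet in this cell preparation. The authors' deposited table held 2386 genes, of which 1882 were protein-coding, each with 1 fold change for the whole comparison. Mean normalized counts of listed genes ran from 0.93 to 64680. The series design gives 4 mice per diet. The groups are written WDV and NDV in the header and name of the table, with the V not explained, and were taken to be the WD and ND libraries. Values of single libraries and their depths were not analysed here, so every error below is the authors' standard error (SE) for the whole comparison.

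Far more of the listed genes were lower than higher under western diet, and the falls were larger. In the authors' deposited table, 1464 genes fell and 526 rose at an adjusted p below 0.05, so that 73.6% of the called genes were lower. The median log2 fold change in that table was -2.10 among the lower genes and 1.34 among the higher genes. A log2 fold change beyond 2 in size was found for 794 lower and 79 higher genes of the authors' deposited table. Of 17531 genes tested by the authors, as recovered from the adjusted p-values, at least 5103 had an adjusted p below 0.05. At least 3113 of these are not in the table, so the counts above describe changes of more than 2-fold only. With a 95% interval wholly beyond 2-fold, a limit chosen after the data were seen, 949 lower and 114 higher genes were left. The 100 genes with the smallest p-values were all in the table and all lower.

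The smallest p-value belonged to Igfbp4, an insulin-like growth factor binding protein gene (ENSMUSG00000017493, chromosome 11, 99041244 to 99054392, mm10), whose log2 fold change in the authors' deposited table was -2.62 ± 0.12 with an adjusted p of 2.35e-98. Cldn5, the tight junction gene of endothelium (ENSMUSG00000041378, chromosome 16, 18776847 to 18778262), fell 17.4-fold in the authors' deposited table (log2 -4.12 ± 0.20, adjusted p 9.90e-94). The largest fall among genes of at least median mean count was that of Rab3b, a vesicle trafficking gene (chromosome 4, 108879063 to 108943324), at log2 -5.57 ± 0.48 in the authors' deposited table. Next in size in that table came Tbxa2r, the thromboxane receptor, at -4.71 ± 0.34, and Ackr4, an atypical chemokine receptor, at -4.17 ± 0.37. The authors' deposited table also placed Sox17 (-4.11 ± 0.25), an endothelial transcription factor, and Bmp6 (-4.09 ± 0.45), a regulator of hepatic iron handling, among the 10 largest falls. Tmem44, Prickle1, Exoc3l2 and Chst2 completed the 10, with log2 fold changes from -3.97 to -3.90 in the authors' deposited table.

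Transcripts of liver sinusoidal endothelial cells, which line the hepatic capillaries beside macrophages, fell as a complete group. All 20 genes of the fixed list were lower in the authors' deposited table at an adjusted p below 0.05. For this and every other fixed list the counts adjusted over the list alone were the same, except for T and NK cell markers and hepatocyte markers, given below. The median log2 fold change of the 20 endothelial genes was -3.16, with a range from -3.85 to -1.49, in the authors' deposited table. By the smallest p, the leading members in that table were Egfl7 (-3.50 ± 0.20), a secreted endothelial factor, Fam167b (-3.85 ± 0.26), Bmp2 (-3.10 ± 0.23) and Tie1 (-3.08 ± 0.23), an angiopoietin pathway receptor. The 5 members with the highest mean normalized counts in the authors' deposited table were Ptprb (6209), the scavenger receptor gene Stab2 (5758), Kdr, the main VEGF receptor gene (5064), the nuclease gene Dnase1l3 (4743) and the lectin gene Clec4g (4553). In that order they fell 9.28-fold, 6.53-fold, 12.1-fold, 5.99-fold and 11.6-fold in the authors' deposited table. Only 1.67 of 20 genes would be called lower at the rate of all 17531 tested genes (hypergeometric adjusted p = 1.59e-20). The list was also more often lower than other listed genes (Fisher's exact test, adjusted p = 0.00481).

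**Figure D1:**
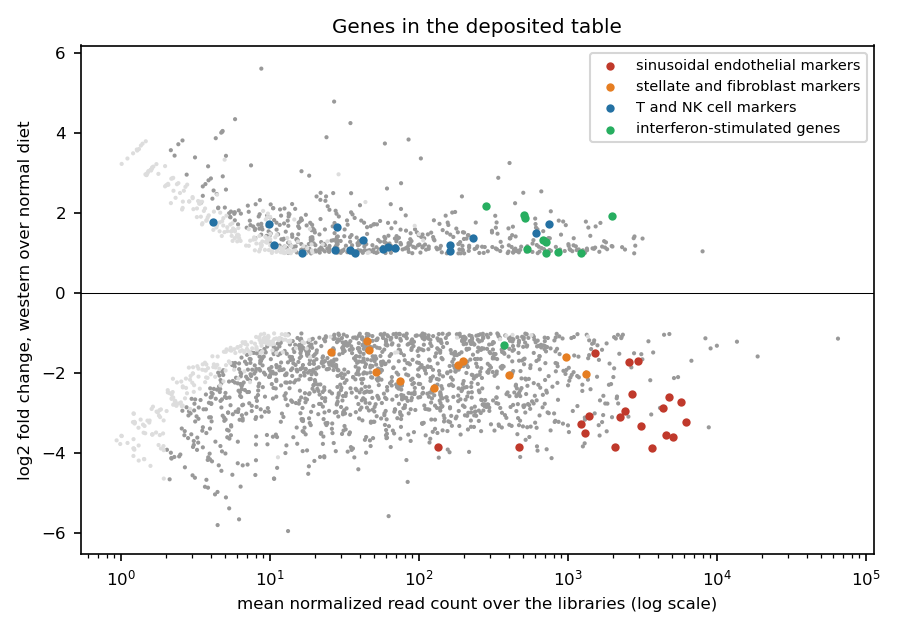
Log2 fold change of each gene in the authors' deposited table (western over normal diet) against its mean normalized read count on a log axis. Dark grey points have an adjusted p below 0.05, light grey points do not, and the band between -1 and 1 is empty because the table was filtered. All 20 sinusoidal endothelial markers (red) lie below 0, as do the 11 listed stellate and fibroblast markers (orange), and all 17 listed T and NK cell markers (blue) lie above it, as do 10 of 11 listed interferon-stimulated genes (green).

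Part of the stellate cell, fibroblast and matrix genes were lower too. Of 20 stellate and fibroblast markers, 11 fell in the authors' deposited table, none rose and 9 were not listed. Among them in that table were Bgn, the proteoglycan biglycan, at -2.01 ± 0.22, Lrat, a retinol esterification gene, at -2.19 ± 0.42, and Vipr1 at -1.79 ± 0.35. Of 30 matrix and fibrosis genes, 10 fell and none rose in the authors' deposited table; Bgn is in both lists. They included Sparc (-2.58 ± 0.20), Timp3 (-2.30 ± 0.22) and the basement membrane collagen gene Col4a1 (-2.09 ± 0.23), each with its value from the authors' deposited table. The collagen genes Col1a1, Col1a2 and Col3a1 are members of both lists but were not in the table. Fn1, the fibronectin gene and the most abundant listed transcript, fell 2.19-fold in the authors' deposited table. Both lists exceeded the rate among tested genes (hypergeometric adjusted p = 1.45e-06 and 0.000837). Their direction differed from other listed genes by a narrow margin (Fisher's exact test, adjusted p = 0.0452 for each), and no longer did when only genes with an adjusted p below 0.05 were compared (0.0864 for each). Sinusoidal endothelial markers fell in the same comparison.

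Part of the interferon-stimulated genes rose. Of 30 fixed genes, 10 were higher and 1 was lower in the authors' deposited table and 19 were not listed. Mx1, an antiviral GTPase gene (chromosome 16, 97447035 to 97462907), rose 4.58-fold in the authors' deposited table (log2 2.20 ± 0.25, adjusted p 3.87e-17). The authors' deposited table gave Oas3, a double-stranded RNA sensor gene, 1.89 ± 0.20, the nucleic acid sensor gene Zbp1 1.96 ± 0.25 and Ifi27l2a 1.04 ± 0.15. Mx2, a paralog of Mx1, was the exception, at -1.30 ± 0.26 in the authors' deposited table. The list was higher more often than other listed genes (Fisher's exact test, adjusted p = 0.000198) and than tested genes (hypergeometric adjusted p = 2.09e-07). T and NK cell markers, 14 of which rose, moved in the same direction, as did 8 dendritic cell markers.

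Cytokine genes moved in both directions. Of 32 cytokines and related effectors, 8 rose, 3 fell and 21 were not listed in the authors' deposited table. Their direction differed from that of other listed genes (Fisher's exact test, adjusted p = 0.00765). This reference is not an even split, since 70.4% of all listed genes were lower. In the same comparison 14 T and NK cell markers and 8 dendritic cell markers rose, and Ccl5 is in both the cytokine and the T and NK cell list. Il12b, a subunit of interleukin-12 (chromosome 11, 44400063 to 44414033), rose 5.37-fold in the authors' deposited table (log2 2.43 ± 0.31). In that table Ccl22, a ligand of the chemokine receptor CCR4, stood at 2.05 ± 0.26. Nos2, the inducible nitric oxide synthase gene, had the higher value of 3.26 in the authors' deposited table, but with an SE of 1.02 (adjusted p 0.00724). The acute phase gene Saa3 (-2.09 ± 0.24) and the interferon-induced chemokine gene Cxcl10 (-1.51 ± 0.20) fell in the authors' deposited table. Of 21 antigen presentation genes, 3 rose and none fell in the authors' deposited table: Nlrc5 (1.82 ± 0.20) and Ciita (1.65 ± 0.19), the master regulators of class I and class II genes, and the co-stimulatory gene Cd86 (1.16 ± 0.12). This was not above the rate among tested genes (hypergeometric adjusted p = 0.158). Of 24 inflammasome and NF-kB genes, Tlr9 rose (1.52 ± 0.18) and Socs3 fell (-1.48 ± 0.16) in the authors' deposited table.

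Among listed markers of recruited monocytes, more were higher than lower. Of 20 fixed genes, 6 rose, 2 fell (Fn1 and Hp) and 12 were not listed in the authors' deposited table. Ms4a4c (2.52 ± 0.25), Plac8 (1.76 ± 0.18), the integrin gene Itga4 (1.28 ± 0.15) and Ccr2, the receptor by which monocytes leave bone marrow (1.44 ± 0.20), led the list in the authors' deposited table. Ly6c2, the classical monocyte antigen gene, was also among the 10 largest rises of the authors' deposited table, at 2.55 ± 0.50. The list differed in direction from other listed genes (Fisher's exact test, adjusted p = 0.0173). Dendritic cell markers followed the same direction, with 8 higher and 1 lower of 20 in the authors' deposited table (Fisher's exact test, adjusted p = 0.00127). In that table Ccr7, which guides migrating dendritic cells, stood at 1.80 ± 0.27, Klrb1b at 1.77 ± 0.29 and Cd209a at 1.38 ± 0.23, whereas the transcription factor gene Zbtb46 stood at -1.13 ± 0.14. T and NK cell markers rose in the same comparison as the monocyte and dendritic cell markers, and sinusoidal endothelial markers, like Zbtb46, fell.

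The T and NK cell markers that passed were all higher. Of 28 fixed genes, 17 were listed and all 17 had positive fold changes in the authors' deposited table. Of these, 14 passed an adjusted p of 0.05 over all tested genes and 15 when adjusted over the list alone. Klrd1 (1.38 ± 0.21), the granzyme gene Gzmb (1.51 ± 0.24), Ccl5 (1.73 ± 0.29) and the NK receptor gene Ncr1 (1.34 ± 0.30) led by p in the authors' deposited table. The list differed in direction from other listed genes (Fisher's exact test, adjusted p = 8.91e-09). It also exceeded the rate among tested genes (hypergeometric adjusted p = 3.64e-13). Of B and plasma cell markers, Ighm (1.17 ± 0.24) and Ms4a1 (adjusted p 0.0196) rose in the authors' deposited table and 17 of 19 were not listed. Immunoglobulin and T cell receptor segments were called higher in 23 cases and lower in 1 case of the authors' deposited table. The 23 include Ighm, Trbc1 and Trbc2, which are also members of the B cell or T and NK cell lists. The 40 listed segments with a positive fold change had a median mean count of 15.6. Mast cell protease genes made up the largest rises among genes of at least median mean count: Tpsb2 (3.85 ± 0.89), Cpa3 (3.75 ± 0.74) and Cma1 (3.38 ± 0.64) in the authors' deposited table. Ly6i, Kctd19 and the granzyme gene Gzmc, at 2.89 ± 0.68, 2.76 ± 0.37 and 2.62 ± 0.37 in the authors' deposited table, were also among the 10, with Nos2, Ly6c2, Ms4a4c and Il12b.

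**Figure D2:**
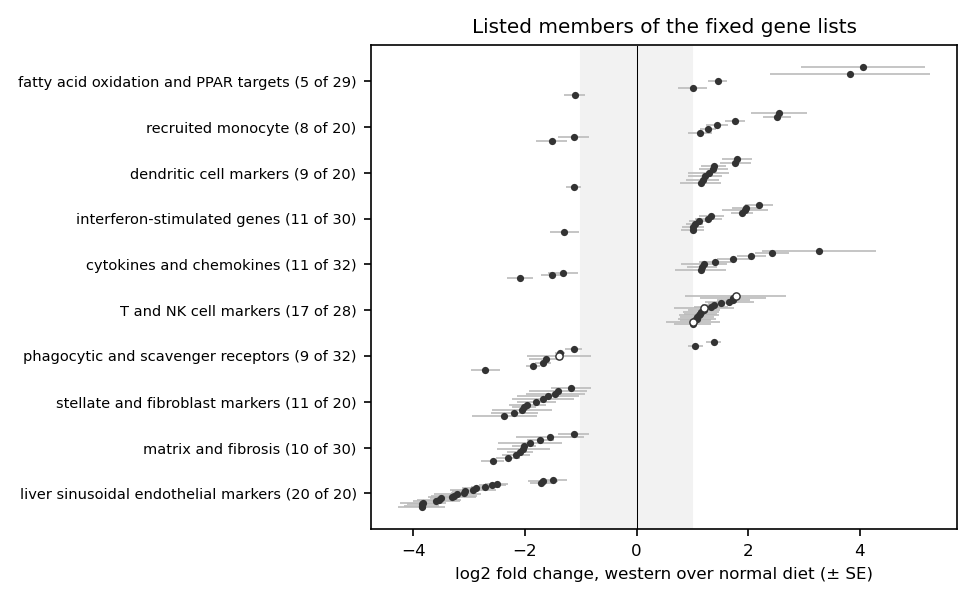
Log2 fold changes (western over normal diet, horizontal axis, bars are the authors' SE) of listed members of each fixed gene list with at least 5 members in the authors' deposited table; list labels give listed and total members. Filled points have an adjusted p below 0.05, open points do not, and the shaded band is the range the table leaves out. Endothelial, stellate and matrix lists hold values below 0 only, and the T and NK cell list holds values above 0 only.

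Most genes that define resident Kupffer cells were not in the table. Of 22 identity genes, Il18bp rose (1.11 ± 0.18) and Cdh5, which endothelial cells also use, fell (-1.68 ± 0.27) in the authors' deposited table. The other 20, among them Adgre1, Clec4f and Timd4, were not listed. None of 22 lipid-associated macrophage genes was listed. Phagocytic and scavenger receptors had 2 genes higher and 6 lower of 32 in the authors' deposited table, which was not a different direction from other listed genes (Fisher's exact test, adjusted p = 1). Gas6 (-1.86 ± 0.12), a bridging ligand for dying cells, the inhibitory Fc receptor gene Fcgr2b (-1.38 ± 0.091) and Stab1 (-1.68 ± 0.14) fell in the authors' deposited table. The activating Fc receptor gene Fcgr1 rose (1.38 ± 0.13) in the authors' deposited table. Fcgr2b and Stab1 are also used by sinusoidal endothelium, whose markers fell in the same comparison. Of 19 alternative activation genes, Pparg (1.45 ± 0.17) and Ccl22 rose while Mrc1 (-1.12 ± 0.15) and Arg1 (-1.21 ± 0.25) fell in the authors' deposited table. Which cells in the preparation these changes came from was not tested, so they cannot be read as a change of macrophage state.

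Lipid metabolism genes were mostly outside the table. Of 29 fatty acid oxidation and PPAR target genes, 4 rose and 1 fell in the authors' deposited table. Their direction differed from that of other listed genes, most of which were lower (Fisher's exact test, adjusted p = 0.0416). The list did not exceed the rate among tested genes (hypergeometric adjusted p = 0.0770). The 4 higher genes were Pparg, Acot1 (adjusted p 0.000934), Cyp4a10 (4.06 ± 1.11) and Cyp4a14 (3.83 ± 1.44), the last 2 at mean counts of 4.80 and 2.58 in the authors' deposited table. Some hepatocyte markers, given below, rose in the same comparison, and which cells these transcripts came from was not tested. Pdk4, which restrains glucose oxidation, fell by 1.11 ± 0.19 on the log2 scale in the authors' deposited table. Of 32 fatty acid synthesis and lipid droplet genes, 1 rose and 1 fell. Scd1, the stearoyl-CoA desaturase gene, rose 3.19-fold (1.67 ± 0.23), and Acacb, an acetyl-CoA carboxylase gene, fell 9.49-fold (-3.25 ± 0.41) in the authors' deposited table. Of 25 cholesterol synthesis genes, Stard4 alone was listed, at -1.64 ± 0.14 in the authors' deposited table. Ch25h was the single listed member of 19 efflux and LXR target genes, at -1.12 ± 0.37 in the authors' deposited table. Ctsl, Pfkm, Atf5 and Epor were the only called members of the lysosome (32 genes), glycolysis (26), stress response (26) and erythroid and platelet (19) lists, with log2 fold changes of -1.31, -1.09, -1.07 and -2.01 in the authors' deposited table. Of 30 hepatocyte markers, Cyp3a11 (3.91 ± 0.71), Ass1 (1.19 ± 0.16) and Apob (1.71 ± 0.62) rose in the authors' deposited table, and Alb was not listed; 2 of the 3 passed when adjusted over the list alone. This was not above the rate among tested genes (hypergeometric adjusted p = 0.330). Of the iron handling (21 genes) and cholangiocyte (15) lists, Steap4 (-1.11 ± 0.51) and Pkhd1 (1.02 ± 0.50) were in the authors' deposited table without passing. The oxidative phosphorylation (48 genes), cell cycle (33), ribosomal protein (30), antioxidant (24), immediate-early and heat shock (24), autophagy (20) and neutrophil (19) lists had no member in the table.

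The first gene to rise in the order of p-values was Smchd1, a chromatin gene of X chromosome silencing (chromosome 17, 71344489 to 71475343), at rank 112 with 1.31 ± 0.10 (adjusted p 1.66e-34) in the authors' deposited table. The authors' own enrichment covered genes with a positive fold change in their table, including some without an adjusted p below 0.05, and its terms with the smallest p were immune terms. In the authors' deposited table, 132 of 373 GO terms and 47 of 78 KEGG terms had a Benjamini p below 0.05. The GO term immune system process held 62 genes at 10.5-fold enrichment, among them Cd86 and Nlrc5, and 54 of the 62 had an adjusted p below 0.05 in the authors' deposited table. Defense response to virus held 26 genes at 9.61-fold, 25 of them with an adjusted p below 0.05, in the authors' deposited table. Positive regulation of interferon-gamma production held 20 genes at 19.6-fold, and all 20 passed, in the authors' deposited table. The leading KEGG term was cytokine-cytokine receptor interaction, with 31 genes (Benjamini p 5.54e-16), of which 28 had an adjusted p below 0.05, and retinol metabolism was listed with 11 genes, of which 6 had an adjusted p below 0.05 in the authors' deposited table. The authors set the GO enrichments against 39275 annotated genes, not against the 17531 tested genes.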

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

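The counts of called genes rested on the limit set here for the authors' adjusted p, within the authors' own filtered list. At an adjusted p below 0.01, 386 genes were higher and 1293 lower. At an unadjusted p below 0.05, which keeps the authors' whole list, these were 706 and 1680. Requiring a log2 fold change of at least 1 removed no gene, since the table was already filtered on it. With a mean count at or above the median, 289 were higher and 889 lower, by construction fewer genes. Among alternatives added after the data were seen, a 95% interval wholly beyond a log2 fold change of 1 left 114 higher and 949 lower genes, which moved the lower share from 73.6% to 89.3%. Protein-coding genes alone gave 388 and 1287, and leaving out markers of other cell types gave 499 and 1431. The latter setting dropped only members of the 9 fixed marker lists, and further endothelial genes such as Cldn5 and Esam stayed in. It cannot show how many called genes come from other cell types. Of the 10 lists tested, 9 differed in direction from other listed genes. This number was 7 when only genes with an adjusted p below 0.05 were compared, 6 at 0.01, and 7 without Gm and Rik symbols. The stellate and matrix lists lost their call in all 3 settings (adjusted p from 0.0537 to 0.408). The interferon, cytokine, monocyte, dendritic cell, T and NK cell and sinusoidal endothelial lists passed in all 3, and the fatty acid oxidation list in the 2 settings that left it 5 listed members. The added enrichment test called 8 lists. Low counts limit the weakest values, with a median SE of 0.88 in the 25% of listed genes with the lowest mean counts. No paired analysis was possible because the table holds no values per library and the library numbers are not shared between groups. For the same lack of values per library, the planned leaving out of each library, other normalizations and count models, other pseudocounts, medians, the count of non-overlapping genes and other splits of the 8 libraries were not run, so how many genes other divisions of the libraries would give was not examined.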

Other observations

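All tests in this part were chosen after the results were seen, and the gene lists in this paragraph and the next were drawn up after their values were seen. Part of the genes of endothelial signalling fell too. Of 14 such genes, 10 were lower, none higher and 4 not listed in the authors' deposited table. Bmp2, one of the 10, is also in the fixed sinusoidal list. The 10 included Wnt2 (-3.28 ± 0.32) and Wnt9b (-2.43 ± 0.49), the Wnt ligands of the central vein region, Bmp6 (-4.09 ± 0.45), and the Notch genes Dll4 (-3.19 ± 0.19) and Notch4 (-2.84 ± 0.18). Of 25 genes of endothelium in general, 23 were lower and none higher in that table, for example Esam (-3.16 ± 0.22), Erg (-2.99 ± 0.25) and Ramp2 (-3.35 ± 0.26). Only 17 of the 25 are outside the fixed sinusoidal list, of which 15 were lower and 2 not listed. The others, such as Kdr, Tek and Pecam1, were already counted there.

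Some groups of immune receptor genes held more higher than lower members. They were compared beside 14 higher T and NK cell markers. Dendritic cell markers (8 higher, 1 lower) and recruited monocyte markers (6 higher, 2 lower) moved mostly the same way. In the authors' deposited table, 9 of 12 co-inhibitory and co-stimulatory receptors and ligands were higher, none lower and 3 not listed, from Ctla4 (2.03 ± 0.45) and Tigit (1.83 ± 0.32) to Pdcd1 (1.13 ± 0.35). Havcr2, which myeloid cells also use, was the most abundant of them in that table (mean count 1366, log2 fold change 1.65 ± 0.16). Of 12 Toll-like receptor genes, 6 rose, none fell and 6 were not listed in the authors' deposited table, with Tlr11 (2.34 ± 0.50), Tlr9 (1.52 ± 0.18) and Tlr5 (1.47 ± 0.20) highest. Of 10 genes of the IL-12 family and its receptors, 5 rose, 2 fell and 3 were not listed in that table. Besides Il12b, Il12a (1.83 ± 0.57), Il27 (1.41 ± 0.28), Il12rb1 (2.23 ± 0.50) and Il12rb2 (1.89 ± 0.29) rose in the authors' deposited table. Il27ra (-1.40 ± 0.17) and Il6st (-2.12 ± 0.17) fell. Of 14 mast cell genes, 7 rose, with Tpsab1 at 4.02 ± 1.17 and Fcer1a at 1.94 ± 0.62, while Kit fell (-1.74 ± 0.15) in the authors' deposited table. Sinusoidal endothelial markers fell in the same comparison as Kit. Several genes named here had mean counts below the table's median of 37.5. They were Tpsab1 (4.70), Fcer1a (9.53), Il12rb1 (14.0), Il12a (16.3) and Tlr11 (21.7), and also Pdcd1, Tigit, Ctla4, Il27 and Il12rb2.

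For the fall of endothelial transcripts, a larger share of macrophages alone would lower markers of every other cell type, but 14 T and NK cell markers rose. Such a share cannot by itself account for both patterns. T and NK cell transcripts may have risen for a separate reason, so it is not excluded as a part of the fall. A switch from a sinusoidal to another endothelial identity without loss of endothelial RNA would not lower genes used by endothelium in general. All 9 such genes in the fixed list (such as Pecam1, Tek and Kdr) fell, as did 15 of 17 outside it, with 2 not listed. The 9 were picked from a list already seen to fall as a whole, and the 17 after their values were seen. These counts are therefore no independent test of such a switch. A uniform loss with no other source of these transcripts is argued against by folds that differed beyond their SE (Cochran's Q over 20 genes, chi-square with 19 degrees of freedom, p = 2.40e-21), so that some of these transcripts may also come from macrophages or from unlike endothelial cells. Less endothelial RNA in the western diet preparations stays open as a candidate explanation, since the fall of 20 of 20 genes (of which Stab2 and Cdh5 are also in other lists) is the observation that raised it and no independent test was run. Whether diet or the isolation, whose sort or gate is not given in the sources used here, lies behind it was not tested.

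For the rise of T and NK cell transcripts, a smaller share of macrophages alone would raise endothelial markers as well, whereas 20 of them fell. Such a share cannot by itself account for both patterns. Endothelial transcripts may have fallen for a separate reason, so a smaller share of macrophages is not excluded as a part of the rise. More T and NK cell RNA in the western diet preparations stays open, since the 14 of 28 markers that rose, with none lower, are the observation that raised it and no independent test was run. Of these 28, only Ccl5 (mean count 744) is also in another list; the next most abundant in the authors' deposited table were Gzmb (613) and Klrd1 (230). The 11 markers outside the table, among them Cd3d, Cd3e, Cd3g, Cd4 and Lck, may have missed either limit or not been measured. Whether they rose, fell or stayed the same is unknown. Expression of such genes by macrophages themselves, and an effect of diet on the number of lymphocytes, were not tested.

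Hepatocyte transcripts were weighed last. More hepatocyte RNA of unchanged makeup would raise these genes by 1 common fold. The 4 listed markers differed beyond their SE (Cochran's Q over 4 genes, chi-square p = 0.00255), as did the 3 other than Ass1, which macrophages also use (Cochran's Q over 3 genes, chi-square p = 0.0387), from 1.69 for Cyp2e1, which did not pass, to 3.91 for Cyp3a11 in the authors' deposited table. The other 26 of the 30 hepatocyte markers, Alb among them, were not listed. With so few listed markers, all of them kept by the table's fold limit, carried-over hepatocyte RNA and a change of hepatocyte expression cannot be told apart.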
